A study of Mus musculus with 10 samples.

How the data were processed

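The data were whole-transcript microarray values from mouse granulosa cells, with 5 samples from PRKO mice and 5 from PR+/- mice. Each sample was a separate biological pool of cells from 3 animals. Per the labels' protocols, RNA was extracted with Tri Reagent and hybridized as biotin-labelled cRNA. The deposited values are log2 expression values, made by the authors, and the submitters' processing notes name Partek without its version or its steps. The background correction, normalization and probe summarization are not given in the sources used here. The values ran from 1.45 to 14.4, and 0 columns per sample were left unused.

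The table held 35557 probe sets, of which 21789 carried 1 gene symbol, 1621 several and 12147 none. Symbols were checked by Entrez ID against a mouse gene table of assembly GRCm38.p6 (21698 matched, 0 symbols updated), which served for names and the order of genes along chromosomes only. For the 999 genes with more than 1 probe set, the one with the highest mean over the 10 arrays was kept, leaving 19938 genes. Probe sets with several symbols or none were left out of the gene tests and tested apart. Dimness was judged against 1027 olfactory receptor genes, whose median was 4.13 and 95th percentile 5.86. Arrays have no depth, so the number of pools and this background set the precision.

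PRKO was compared with PR+/- with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes moderation, equal array weights, no block). Genes were said to differ at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and adjusted p for genes in the text come from limma. Differences are PRKO minus PR+/- on the log2 scale, with limma's standard error (SE), the standard deviation (SD) being that of the 5 pools. There were 34 lists of 516 entries, of which 475 were measured, fixed before the data were examined, as were the comparison, the threshold, the naming rule and the first set of other settings. List members were also adjusted over their list alone. Lists of at least 5 measured genes were tested with camera at its preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry. The 95% intervals of list means come from the mean of the list in each pool and the SD of the 5 pools of each genotype, not from limma. Calls within 20 Mb of Pgr were compared with calls elsewhere by Fisher's exact test.

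Genes are named by a rule: Pgr, the 12 largest falls and 12 largest rises among genes past the threshold (predicted and clone-named genes left out), and up to 4 members with the smallest p in each list, whether or not they passed. Other genes are said to be named after their values were seen. The pipeline was tested on simulated data with 50 genes planted at each fold. It recovered 28% of changes at 1.25-fold, 84% at 1.5-fold, 100% at 2-fold and 98% at 3-fold. There were 12 false calls among 167, and 0 calls by limma when nothing was planted. Each simulated gene was drawn independently of the others, so these rates do not cover genes that vary together between pools.

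Other settings, chosen before the data were examined, were quantile normalization, median centring, leaving out dim genes (under the 30th percentile), an intensity trend, a robust prior, array weights, the replicate number as a block, the mean of a gene's probe sets, all probe sets, a fold of at least 1.5, an adjusted p under 0.01, exact permutation, leaving out each pool in turn, and windows of 10 and 40 Mb. Added after the main counts were seen were leaving out the least correlated array of each genotype and 2 covariates per array, the olfactory receptor mean and the difference between the luteal and granulosa list means. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.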

Results

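Expression was measured on whole-transcript microarrays in granulosa cells from immature mice that lacked the progesterone receptor (PRKO) and from heterozygous controls (PR+/-). PRKO mice carried a lacZ insertion in both copies of Pgr, the gene of the receptor, and PR+/- mice carried it in 1 copy. The mice were 21 to 23 days old, were primed with equine chorionic gonadotropin (5 IU) to grow follicles and, 44 to 47 h later, given human chorionic gonadotropin (hCG, 5 IU) so that ovulation would start. Antral follicles were punctured 8 h after hCG, and cells from 3 animals were pooled for each array, giving 5 pools per genotype from 15 animals each. The table held log2 expression values for 35557 probe sets, with array medians between 6.48 and 6.55 and pairwise correlations between 0.973 and 0.992 over the 10 arrays. Arrays give no read depth, and with 5 pools per genotype their number limits the precision. The question was which transcripts depended on the receptor in granulosa cells during the ovulatory response.

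Pgr itself, the nuclear receptor for progesterone, was read by 1 probe set (10583179) and did not differ past the threshold. Its log2 value was 6.91 ± 0.70 in PR+/- and 6.45 ± 0.32 in PRKO (SD, n = 5 pools each), a log2 difference of -0.46 (95% interval -1.04 to 0.12, limma adjusted p = 0.527). PR+/- pools 1 to 5 read 6.32, 7.70, 6.07, 7.02 and 7.45. PRKO pools 1 to 5 read 6.69, 6.26, 6.27, 6.15 and 6.90, so all 5 lay within the range of the controls. The position of its probes relative to the lacZ insertion is not given in the sources used here, so this probe set neither checks the genotype labels nor goes against them.

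PRKO granulosa cells had much less of several transcripts that were abundant in the controls. Zbtb16, a zinc finger transcription factor inducible by progestins and glucocorticoids, was 10.7-fold lower in PRKO, with a log2 value of 10.15 ± 0.23 in PR+/- and 6.73 ± 0.41 in PRKO (SD, n = 5 pools each). Slc7a11, the cystine importer that feeds glutathione synthesis, was 6.54-fold lower (log2 difference -2.71, SE 0.12). Hsd17b11, a lipid droplet enzyme of the 17-beta-hydroxysteroid dehydrogenase family, was 5.69-fold lower (log2 difference -2.51, SE 0.09), and Gpt2, the mitochondrial alanine aminotransferase, was 3.90-fold lower (log2 difference -1.96, SE 0.09). Adjusted p from limma for these 4 genes lay between 3.58e-09 and 5.86e-08.

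Other large falls were in Tmem100 (log2 difference -1.99, with PRKO pool 5 apart from the rest at 5.86), the ubiquitin ligase Rnf125 (-1.88), Gas7 (-1.76), the membrane fusion protein Snap25 (-1.76, with PRKO pool 3 apart at 6.39), the chemokine receptor Cxcr4 (-1.75) and Tbc1d8 (-1.73). SE of these 6 differences were 0.09 to 0.17 and the highest adjusted p was 9.80e-06. Sprr2g and Apela, a peptide ligand of the apelin receptor, also fell, from 6.36 to 4.29 and from 6.01 to 4.24. Both PRKO means lay under 5.86, the 95th percentile of olfactory receptor genes, which stand here for background signal, so the sizes of these 2 falls (-2.07 and -1.77 as read) are uncertain. For all 12 of these genes, the PRKO and PR+/- pools did not overlap.

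Fewer genes were higher in PRKO, and by smaller amounts. Npr3, the natriuretic peptide clearance receptor, was 2.95-fold higher, from 7.82 ± 0.48 to 9.38 ± 0.31 on the log2 scale (SD, n = 5 pools each, limma adjusted p = 0.000374). Sfrp2, a secreted modulator of WNT signalling, was 2.89-fold higher (log2 difference 1.53, SE 0.17, adjusted p = 1.00e-04), and Olfml2b, a secreted olfactomedin-like protein, was 2.51-fold higher (1.33, SE 0.16, adjusted p = 0.000214). The bone morphogenetic protein co-receptor Rgmb rose by 0.97, the prolyl hydroxylase Egln3 by 0.96, the protease Pappa, which cleaves insulin-like growth factor binding proteins, by 0.85, the ephrin receptor Epha5 by 0.84, the Ras regulator Rasal1 by 0.81 and the kinase Nuak1 by 0.79 on the log2 scale, with SE of 0.09 to 0.15. Cited4, a transcriptional coactivator, rose by 0.86, with PRKO pool 5 apart at 11.3, and in Epha5 PRKO pool 1 lay apart at 8.03. Msc and Ddit4l also passed (log2 differences 1.04 and 0.99, adjusted p = 0.0330 and 0.0234). Their calls were lost without any 1 of 7 pools for Msc (PR+/- 1 to 4, PRKO 1, 2 or 4, adjusted p up to 0.0950) and of 4 pools for Ddit4l (PR+/- 1, PRKO 1 to 3, adjusted p up to 0.0694).

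**Figure D1:**
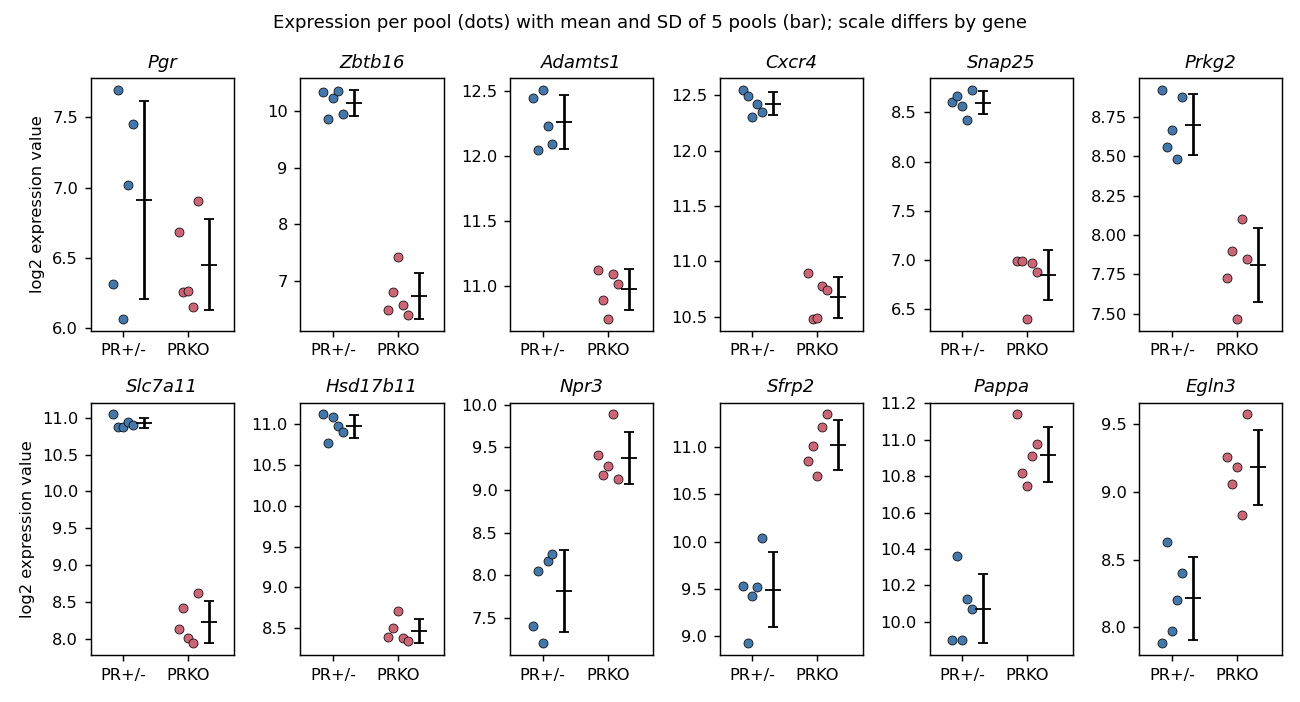
Log2 expression value (y axis, scale differing by gene) of 12 genes in the 5 PR+/- pools (blue dots) and the 5 PRKO pools (red dots), with the mean and SD of each genotype as a black bar. The genotypes overlap in Pgr, while in Zbtb16 all PRKO pools lie at least 2.44 below the lowest PR+/- pool.

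Across all 19938 genes tested with limma, 491 (2.46%) differed at an adjusted p under 0.05, of which 341 were lower and 150 higher in PRKO. Among those lower, 63 fell at least 2-fold and the median log2 difference was -0.60. Among those higher, 4 (Npr3, Sfrp2, Olfml2b and Msc) rose at least 2-fold and the median was 0.46. The PRKO and PR+/- pools did not overlap in 442 of the 491 genes, and in 4.42% of all genes tested against 0.794% by chance. The median log2 difference over all genes was -0.02. The count of higher genes was 92, 85 and 95 without PR+/- pool 1, 3 or 4, and 89 and 93 without PRKO pool 1 or 5.

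**Figure D2:**
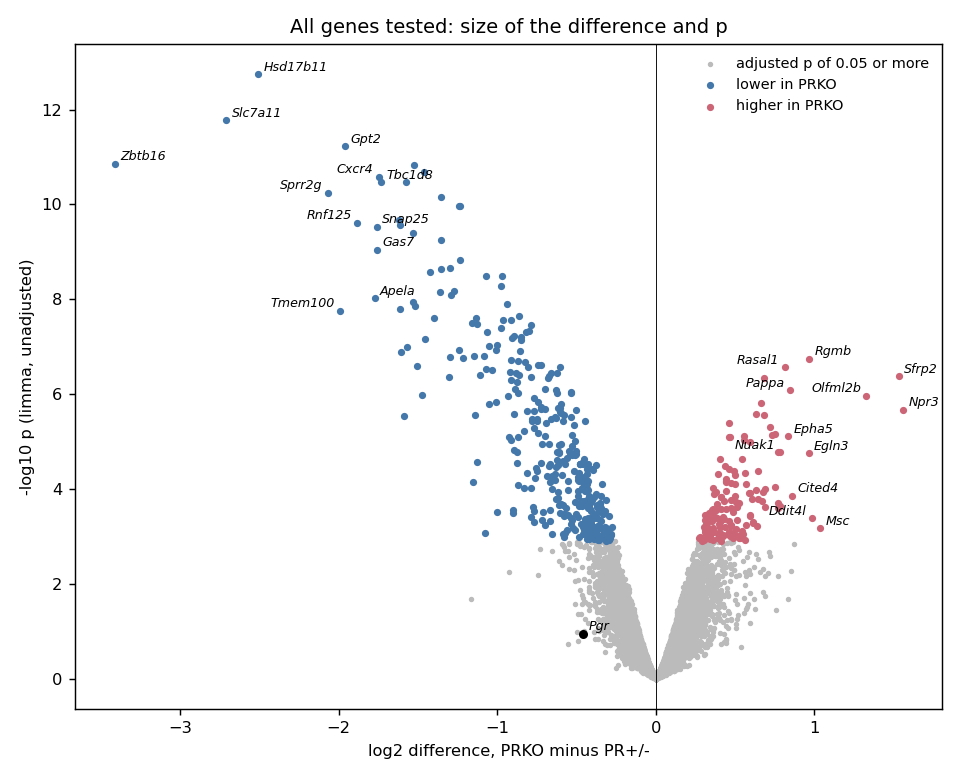
Log2 difference between PRKO and PR+/- (x axis) against -log10 of the unadjusted limma p (y axis) for each gene tested, with genes past the adjusted threshold in blue (341 lower in PRKO) and red (150 higher). The named points are the genes with the largest falls and rises and, in black, Pgr, which lies among the grey points that did not pass.

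Most genes known to need the progesterone receptor at ovulation fell. Of 14 measured members of this list, 9 fell over all genes and 10 adjusted over the list alone, and the mean log2 difference was -0.98 (camera adjusted p = 7.06e-21, and adjusted p = 0.00161 with an estimated correlation). Besides Zbtb16, Cxcr4 and Snap25, the list held falls in Epas1, a hypoxia-inducible transcription factor subunit (-1.51, SE 0.16), and in Adamts1, the protease that cleaves versican in the expanding cumulus matrix (-1.29, SE 0.11, from 12.26 ± 0.21 to 10.97 ± 0.16, SD). Prkg2, a cyclic GMP dependent kinase, fell by 0.90, the nuclear receptor Pparg by 0.88 and cathepsin L (Ctsl) by 0.43 on the log2 scale. A dimmer probe set of Prkg2 (mean 5.04) gave -0.52 with an adjusted p of 0.284 over all probe sets. Il6, dim in both genotypes, read 0.79 lower, a fall of uncertain size. Its call was lost without PR+/- pool 1, 3 or 5 or PRKO pool 1, 2 or 3 (limma adjusted p up to 0.0707). Edn2, the endothelin associated with follicle rupture, had a log2 difference of -0.57 (adjusted p = 0.0695) and passed over the list alone. The other 4 members, named after their values were seen, passed on neither adjustment: Hif1a (-0.19), Fkbp5 (-0.18), Ereg (-0.25) and Adcyap1, which had the opposite sign (0.18).

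**Figure D3:**
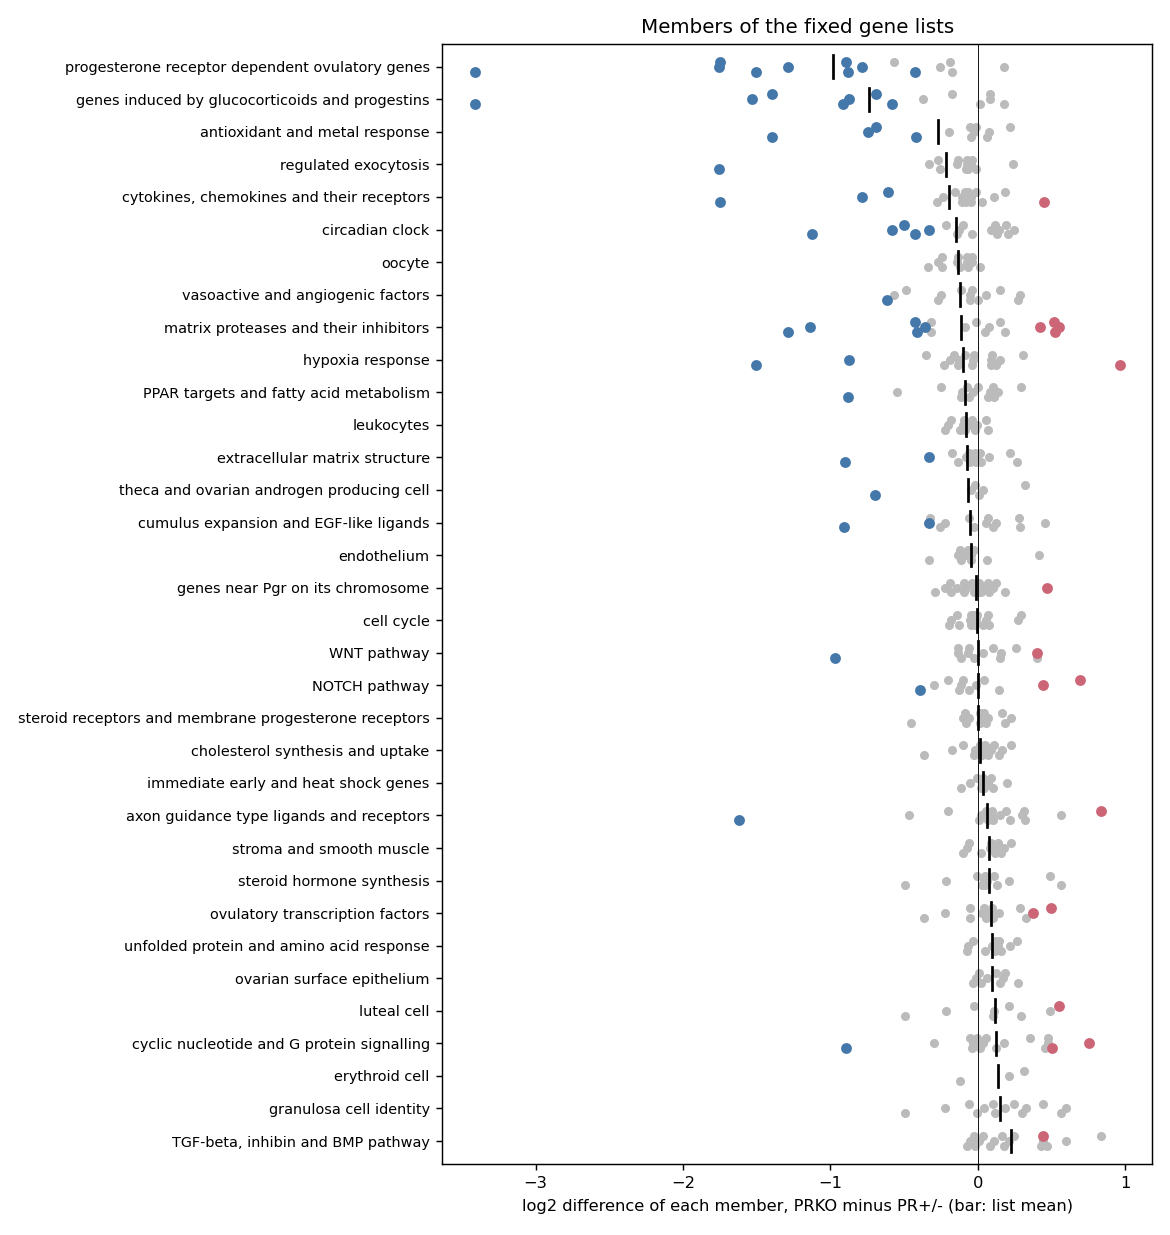
Log2 difference between PRKO and PR+/- (x axis) of each measured member of the 34 fixed gene lists (y axis), with members past the threshold over all genes in blue (lower) or red (higher), the others in grey, and the list mean as a black bar. The list of progesterone receptor dependent ovulatory genes has the lowest mean, -0.98.

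Genes inducible by glucocorticoids and progestins had the next lowest list mean. Of 13 measured members, 7 fell over all genes and 8 adjusted over the list alone, with a mean log2 difference of -0.74 (camera adjusted p = 9.58e-12, adjusted p = 0.0557 with an estimated correlation). These were Zbtb16, which the list shares with the progesterone receptor dependent genes, Tsc22d3 (-1.53, SE 0.10), known as a glucocorticoid-induced leucine zipper, the metallothioneins Mt2 (-1.40, SE 0.12) and Mt1 (-0.69, SE 0.09, with PRKO pool 5 apart at 11.1), the transcription factor Klf9 (-0.92), Ddit4 (-0.87), an inhibitor of mTOR signalling, and the clock gene Per1 (-0.58).

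The antioxidant and metal response list had 4 of 12 members lower over all genes and 4 adjusted over the list alone (mean -0.27, camera adjusted p = 0.00648, adjusted p = 0.338 with an estimated correlation). They were both metallothioneins, Gclc, the catalytic subunit of the first enzyme of glutathione synthesis (-0.74, SE 0.08, with PR+/- pool 3 apart at 10.7), and Gsta4 (-0.42). The Gsta4 call was lost without PR+/- pool 1, 2, 4 or 5 or PRKO pool 4 or 5 (adjusted p up to 0.0839).

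In the circadian clock list, 5 of 17 members fell over all genes and 5 adjusted over the list alone (mean -0.15, camera adjusted p = 0.0288, adjusted p = 0.489 with an estimated correlation). They were Rora (-1.13, SE 0.18), Per1, Per2 (-0.50), Nfil3 (-0.42) and Cry1 (-0.33), the last named after its values were seen and lost without PR+/- pool 4 or 5 or PRKO pool 2 or 4 (adjusted p up to 0.0585). The camera call was lost without PR+/- pool 1 or 3 or PRKO pool 2, 3 or 4 (adjusted p up to 0.0576).

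Among cytokines, chemokines and their receptors, Cxcr4, Il6 and the leukaemia inhibitory factor Lif (-0.61, SE 0.09) fell, Il6 being dim in both genotypes and Lif in PRKO (means under 5.86), while Cxcl12, the ligand of Cxcr4, rose by 0.45 on the log2 scale (SE 0.08). Of 19 members, 4 thus changed over all genes and 6 adjusted over the list alone, 5 lower and 1 higher (mean -0.19, camera adjusted p = 0.0233, adjusted p = 0.415 with an estimated correlation, and 0.0504 with the preset correlation without PR+/- pool 3). The regulated exocytosis list (mean -0.22, camera adjusted p = 0.00648, adjusted p = 0.415 with an estimated correlation) held 14 members, of which Snap25 alone fell over all genes and 4 passed adjusted over the list alone, 3 lower and 1 higher. Its next members by p, Vamp1, Rab3a and Scg2, had log2 differences of -0.33, 0.24 and -0.27, Scg2 being dim in both genotypes.

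Matrix proteases and their inhibitors went both ways, with 5 of 17 lower and 4 higher over all genes and 6 lower and 5 higher adjusted over the list alone (camera adjusted p = 0.497). Adamts1, Ctsl and the matrix metalloproteinase Mmp19 (-1.14, SE 0.15) fell, and the metalloproteinase inhibitor Timp3 rose by 0.52 on the log2 scale (SE 0.10). Named after their values were seen, Mmp14 (-0.41) and Adamts4 (-0.36) were also lower, and the plasminogen activators Plau (0.51) and Plat (0.42) higher, with limma adjusted p of 0.0346, 0.0424, 0.0162 and 0.0421. These calls were lost without any 1 of 7 pools for Mmp14 (all but PR+/- 2, PRKO 2 and 4, adjusted p up to 0.103), 8 for Adamts4 (all but PR+/- 2 and PRKO 4, up to 0.116), 8 for Plat (all but PRKO 2 and 3, up to 0.107) and 3 for Plau (PR+/- 3 or 4 or PRKO 1, up to 0.0525). Of the 9 calls, 4 or 5 were left without PR+/- pool 3, 4 or 5 or PRKO pool 1 or 5. Timp1 passed as higher (0.55, adjusted p = 0.0406), a call lost without PR+/- pool 2, 3, 4 or 5 or PRKO pool 1, 2, 4 or 5 (adjusted p up to 0.113). Among cumulus expansion genes, 2 of 14 fell over all genes and adjusted over the list alone, the epidermal growth factor receptor Egfr (-0.91, SE 0.08) and the proteoglycan versican, Vcan (-0.33, SE 0.07). Has2 (-0.32) and Cd44 (0.28) did not pass, nor did the cumulus list (camera adjusted p = 0.497). In the extracellular matrix list, 2 of 16 members fell over all genes and adjusted over the list alone, Vcan and the collagen cross-linking enzyme Lox (-0.90, SE 0.19, with PR+/- pool 5 apart at 9.03), and the list did not pass (camera adjusted p = 0.497). The Vcan call was lost without PR+/- pool 1, 4 or 5 or PRKO pool 2 (adjusted p up to 0.0684), and that of Lox without PRKO pool 1 (0.0501).

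Transcripts of steroid and cholesterol synthesis did not differ past the threshold. In limma, no member of the steroid hormone synthesis list passed over all genes (13 measured, 3 at an unadjusted p under 0.05), and 1, Hsd3b1, passed adjusted over the list alone (camera adjusted p = 0.135). Hsd3b1 had a log2 difference of 0.49 (SE 0.13, adjusted p = 0.0706), Cyp11a1, the side chain cleavage enzyme, 0.21 (SE 0.09), and Star, which brings cholesterol into mitochondria, -0.21 (SE 0.11). Of 15 cholesterol genes, none passed over all genes or over the list alone in limma (2 at an unadjusted p under 0.05, camera adjusted p = 0.497), and Dhcr7 had the smallest p (-0.36, SE 0.12). Among 14 steroid receptors and membrane progesterone receptors, none passed in limma over all genes or over the list alone (1 at an unadjusted p under 0.05, camera adjusted p = 0.497), with Pgrmc1 at 0.23 and Paqr7 at 0.18.

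In the hypoxia response list, Epas1 and Ddit4 fell and Egln3 rose, 3 of 19 members over all genes and 4 adjusted over the list alone (camera adjusted p = 0.374), and Bnip3 had a log2 difference of -0.35 (SE 0.12). Of 14 vasoactive and angiogenic factors, angiotensin converting enzyme, Ace, fell by 0.62 on the log2 scale (SE 0.12), the 1 call over all genes against 4 adjusted over the list alone (camera adjusted p = 0.125). Apln had a log2 difference of -0.48 and Ece1 of -0.27. Pparg was the 1 of 15 PPAR and fatty acid genes that fell over all genes. With Fabp4 (-0.55, with both means under the background level of 5.86 and PR+/- pool 5 apart at 6.01), 2 passed adjusted over the list alone (camera adjusted p = 0.497).

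In 3 lists of signalling genes that passed as higher with camera's preset correlation, few members rose, and none of the 3 passed with an estimated correlation or with fry (adjusted p = 0.136, 0.218 and 0.370 in the order below). The TGF-beta, inhibin and BMP list had a mean log2 difference of 0.23 (camera adjusted p = 0.000624, adjusted p = 0.380 with an estimated correlation). Of its 18 members, Bambi, a pseudoreceptor of the family, alone rose over all genes (0.44, SE 0.08) and 3 adjusted over the list alone. Id3 stood at 0.47 (SE 0.13), and the inhibin subunits Inha and Inhba at 0.24 (SE 0.08) and 0.60 (SE 0.22). In the cyclic nucleotide and G protein list, Prkg2 fell and the phosphodiesterases Pde10a (0.75, SE 0.14) and Pde4b (0.50, SE 0.10) rose, 3 of 17 over all genes and 6 adjusted over the list alone, 2 lower and 4 higher. Its camera adjusted p was 0.0480 (adjusted p = 0.415 with an estimated correlation), lost without PR+/- pool 1 or 3 or PRKO pool 2, 3 or 4 (up to 0.120). In the axon guidance type list, the ephrin ligand Efnb2 fell by 1.62 on the log2 scale (SE 0.10) and Epha5 rose, 2 of 18 over all genes and 6 adjusted over the list alone, 1 lower and 5 higher. Slit2 and Sema3e had values of 0.56 and 0.32. That list passed as higher with a mean of 0.06 (95% interval -0.05 to 0.17, camera adjusted p = 0.0283, adjusted p = 0.415 with an estimated correlation), a call lost without PR+/- pool 3 or PRKO pool 2 or 4 (up to 0.0885).

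In the NOTCH pathway, Notch1 (0.44, SE 0.08) and its target Hey1 (0.69, SE 0.13) rose and Heyl fell by 0.39 on the log2 scale, 3 of 12 members over all genes and 4 adjusted over the list alone, 2 lower and 2 higher (camera adjusted p = 0.802). In the WNT pathway, the receptor Fzd1 fell by 0.97 (SE 0.07) and Fzd4 rose by 0.40 (SE 0.09) on the log2 scale, 2 of 14 members over all genes and 3 adjusted over the list alone (camera adjusted p = 0.750). The calls of Heyl and Fzd4 were lost without any 1 of 8 and 7 pools (adjusted p up to 0.123 and 0.112), which for Heyl were all but PR+/- pool 1 and PRKO pool 2 and for Fzd4 all but PR+/- pools 1 and 5 and PRKO pool 2. Of 15 ovulatory transcription factors, Fosl2 (0.50, SE 0.09) and the corepressor Nrip1 (0.37, SE 0.08) rose over all genes, and 3 passed adjusted over the list alone, 1 lower and 2 higher. The camera call of that list (adjusted p = 0.0480, adjusted p = 0.639 with an estimated correlation) was lost without any 1 of 7 pools (up to 0.217), which were all but PR+/- pool 5 and PRKO pools 2 and 4. The Nrip1 call was lost without PR+/- pool 3, 4 or 5 or PRKO pool 1 or 2 (adjusted p up to 0.0665).

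Of the markers of the granulosa and luteal states, only Timp1 passed over all genes, and the intervals of both list means were wide. No member of the granulosa cell identity list passed over all genes in limma (14 measured, 6 at an unadjusted p under 0.05), and 5 passed adjusted over the list alone, Foxl2 (0.30), Amhr2 (0.33), Hsd17b1 (0.56), Inha and Inhba, all higher. The list mean was 0.15 (95% interval -0.18 to 0.49, camera adjusted p = 0.0283, adjusted p = 0.732 with an estimated correlation), and the call was lost without PR+/- pool 1, 3 or 5 or PRKO pool 2 or 3 (up to 0.193). Of 9 luteal cell genes, Timp1 passed over all genes and 3 adjusted over the list alone, with Hsd3b1 and Cdkn1b, and the list mean was 0.11 (95% interval -0.17 to 0.40, camera adjusted p = 0.0283, adjusted p = 0.647 with an estimated correlation). That call was lost without PR+/- pool 2 or 3 or PRKO pool 1, 4 or 5 (up to 0.127).

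Markers of other cell types gave 1 call among 68 measured genes. Hhip, a hedgehog binding protein of the theca list, fell by 0.70 on the log2 scale (SE 0.10, 1 of 6 over all genes and over the list alone, camera adjusted p = 0.518), while Aldh1a1, Gli1 and the dim Plac8 had values of 0.32, -0.05 and 0.04. Over all genes and over each list alone, limma called none of 12 stroma and smooth muscle genes (0 at an unadjusted p under 0.05, mean 0.08), 11 endothelial genes (1, mean -0.05), 13 leukocyte genes (2, mean -0.08), 13 oocyte genes (1, mean -0.14) or 10 surface epithelium genes (0, mean 0.09). Their camera adjusted p were 0.420, 0.658, 0.208, 0.135 and 0.221. The endothelium mean was -0.14 without PRKO pool 4, which lay apart at 7.10, and the oocyte mean -0.26 without PRKO pool 2, apart at 8.23. Leaving out 1 pool gave means of -0.04 to 0.18 for stroma, -0.11 to -0.04 for leukocytes, a list with a mean at background, and up to 0.18 for surface epithelium. Examples were Dcn (0.23), Kdr (0.41), Cdh5 (-0.33), the dim Ptprc (-0.21), Krt19 (0.27) and Kit (-0.34). Without PRKO pool 2, which lay apart at 7.80, Kit passed as lower (-0.46, limma adjusted p = 0.0134), the 1 call in the oocyte list. The erythroid list had 3 measured members, too few for a set test, and limma called none of them (0 at an unadjusted p under 0.05), Alas2 standing at 0.21.

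Proliferation and acute stress genes did not pass either. Over all genes and over each list alone, limma called none of 18 cell cycle genes (2 at an unadjusted p under 0.05, camera adjusted p = 0.949), with Pcna at 0.27 and Aurka at -0.20, and none of 11 immediate early and heat shock genes (0 at an unadjusted p under 0.05, camera adjusted p = 0.497), with Fos at 0.10 and Jun at 0.09. In the unfolded protein and amino acid response list, limma likewise called none of 12 members (0 at an unadjusted p under 0.05), with Ddit3 at 0.26, Atf4 at 0.16 and a list mean of 0.09. Its camera adjusted p was 0.0361 (adjusted p = 0.591 with an estimated correlation), lost without PR+/- pool 2, 3 or 4 or PRKO pool 1, 3 or 4 (up to 0.140).

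In windows of 10, 20 and 40 Mb around the disrupted locus on chromosome 9, Fisher's exact test showed no difference in the share of called genes. Within 20 Mb of Pgr, 5 of 196 genes passed, against 484 of 19656 placed genes elsewhere (odds ratio 1.04, 95% interval 0.33 to 2.48, Fisher's exact test, p = 0.817). Within 10 Mb, 4 of 76 genes passed (5.26% against 2.45% elsewhere, odds ratio 2.21, 95% interval 0.58 to 5.94, Fisher's exact test, p = 0.118). The 5 genes were Tmem123 (0.47, with PR+/- pool 3 apart at 9.78) and, named after their values were seen, Gpr83 (-0.76), Amotl1 (-0.64), Maml2 (-0.40) and Igsf9b (-0.34). The calls of Maml2 (all but PRKO pools 1 and 3) and Igsf9b (all but PR+/- pool 1 and PRKO pool 2) were lost without any 1 of 8 pools (adjusted p up to 0.102 and 0.0951). Tmem123 was also the 1 call over all genes among 23 fixed neighbours of Pgr (2 adjusted over the list alone with Birc3 at -0.29, camera adjusted p = 0.807), lost without any 1 of 8 pools (adjusted p up to 0.112), which were all but PR+/- pool 2 and PRKO pool 3.

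Of 33 lists with a set test, 13 passed with camera's preset correlation and 1, the progesterone receptor dependent ovulatory genes, with an estimated correlation. With fry, which asks whether a list's genes move on balance one way, 6 passed, namely the progesterone receptor dependent, glucocorticoid and progestin, antioxidant, cytokine, circadian and exocytosis lists. Mean, median and camera direction differed in sign in the cumulus, WNT, NOTCH and cell cycle lists, which did not pass. Leaving out 1 pool gave a call to 13 named genes that had none with all pools: Apln, Vamp1, Edn2, Birc3, Ece1, Kit and Fabp4 as lower, and Hsd3b1, Prkar2b, Amhr2, Pcna, Foxl2 and Dkk3 as higher.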

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

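Chosen only after the result they bear on was seen were the tests on other cell types, the 3 tests on Pgr, the olfactory receptor covariate, the expression-matched placements and the neighbouring pairs in other splits. For the covariate and the pairs in other splits, what would count against the explanation was written down before their own outcome was seen. Among 100 of the 126 distinct splits of the 10 pools into 5 and 5, 1 split, the real one, gave as many genes past the threshold. It gave 491 and the highest other split 1, so a grouping unrelated to genotype is argued against as the source of the count, at best at 1 in 100. Every other split mixes the genotypes, so any genotype effect widens its residual spread. The counts of those splits are therefore not those of data without an effect.

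More genes were lower (341) than higher (150) in PRKO. Scaling differences left between the deposited arrays, as the whole cause, are argued against by the share of lower genes. It was 69.5% as deposited and 73.5% and 72.2% after quantile normalization and median centring. Since the deposited array medians already lay between 6.48 and 6.55, these steps could move the share little. They cannot judge the normalization made before deposit, whose steps are not given. The background level is argued against by 75.2% with the olfactory receptor mean as a covariate. Fewer theca, stroma, endothelial or surface epithelium cells as the whole cause are argued against by the interval ends of their 4 lists. With all pools or without any 1, the lowest end was -0.47, above the median of the lower genes, -0.60. That median is of genes picked as past the threshold, and the smaller falls among them could still come from such a loss. Fewer oocytes stay open, since that end was -0.62 for the oocyte list, and so do fewer leukocytes or erythroid cells, since the leukocyte list mean in PR+/- minus the background level was -0.042 and the erythroid list had 3 genes; that the receptor mainly raises transcripts at 8 h after hCG was not tested and stays open beside them.

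Pgr did not pass the threshold although it is the disrupted gene. In Zbtb16 a gap of 2.44 parted the genotypes, and the ranges within them were 0.49 and 1.03. Zbtb16 was the largest fall under these same labels and was chosen for this check after that was seen. Its separation therefore cannot decide whether a pool was mislabelled. Zbtb16 also lies within 40 Mb of Pgr on chromosome 9. A large spread of Pgr between pools could explain the missed threshold. Its residual SD (0.55) lay at the 99.8th percentile of the tested genes. At the median residual SD (0.14), an ordinary t test without limma's moderation would have given an unadjusted p of 0.000922. The lowest PR+/- value of Pgr lay 0.20 above the olfactory receptor 95th percentile. By the mark written down for this test, that counts against a probe set close to background. The margin is less than the SD of 0.70 between the PR+/- pools, so closeness to background is left open. Which part of the transcript the probes read was not tested.

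Called genes lay next to one another more often than chance placement gives, with 42 neighbouring pairs among 19851 ordered genes, 3.50 times the number expected under random placement (3.06 times with expression matched, permutation p = 1e-04 for both, the smallest that 10000 placements can give). In 40 pairs the direction was the same (35 lower, 5 higher), as in Hsd17b11 with Nudt9 (-2.51 and -1.45) and Slc7a11 with Pcdh18 (-2.71 and -0.83), the second gene of each pair named after its values were seen. Probes shared between related genes as the whole cause are argued against by the 34 same-direction pairs without a shared symbol stem (5.96 expected). The stem only stands in for relatedness, so related genes with unlike symbols may be among the 34. Of the 42 pairs, 5 overlapped on the chromosome, and signal shared through overlap was not tested. Donor-strain sequence around Pgr as the whole cause is argued against by 0 pairs within 20 Mb, where the odds ratio of calls was 1.04. Within 10 Mb the odds ratio was 2.21 (95% interval 0.58 to 5.94), which alone would leave that explanation open. Neighbours that vary together whatever the genotype are argued against as the whole cause. Among 99 other splits, 0 held as many as 40 same-direction pairs (median 15, highest 31). Random placement of the real calls gives 6.93 such pairs (7.90 with expression matched), so the other splits at their median also held more than that. Those splits mix the genotypes unevenly and do not show how far neighbours vary together apart from genotype. Shared regulation of neighbouring genes by the receptor may remain as a hypothesis, and transcription running on from one gene into the next was not tested.

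A pool lay far from the other 4 of its genotype, by a gap over 0.71 of their range, in 23 of 356 groups tested (6.46%), where chance gives about 1 in 20. In PRKO pool 2 these were Kit (7.80), Ooep (8.16), Zp2 (9.15) and the oocyte list mean (8.23), all highest, and Atf3 (9.16), lowest. PRKO pool 5 was highest in Mt1 (11.1), Cited4 (11.3), Cbfb (10.3) and the antioxidant list mean (9.13), and lowest in Tmem100 (5.86). PRKO pool 4 was highest in the vasoactive (7.17) and endothelium (7.10) list means and lowest in Aurka (8.65). PRKO pool 3 was lowest in Snap25 (6.39) and highest in Aldh1a1 (11.3), and PRKO pool 1 highest in Epha5 (8.03) and Fosb (12.001). PR+/- pool 3 was lowest in Gclc (10.7), Tmem123 (9.78) and Fos (10.5), PR+/- pool 5 highest in Lox (9.03) and Fabp4 (6.01), and PR+/- pool 4 lowest in Upk3b (7.31).

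Outside the gene tests, 109 of 12147 probe sets with no gene symbol passed the threshold in limma (100 lower and 9 higher, log2 differences from -1.90 to 1.05). So did 13 of 1621 with several symbols (5 lower and 8 higher, from -0.998 to 0.748).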

How the results depend on the processing

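Chosen only after the main counts were seen were the tests without both least correlated arrays and with the 2 covariates. Counts of differing, lower and higher genes were 491, 341 and 150 as deposited. They stayed within 1.5 times that with quantile normalization (514, 378, 136), median centring (464, 335, 129), dim genes left out (554, 366, 188 of 14860 tested), an intensity trend (558, 374, 184), a robust prior (489, 340, 149), array weights (598, 398, 200), the mean of probe sets (486, 341, 145), the olfactory covariate (463, 348, 115) and the luteal minus granulosa covariate (614, 394, 220). With all probe sets 90 were higher (455 and 365 differing and lower). That fit adjusted over 35557 rows instead of 19938 and kept 318 of the 491 calls. Its calls included 109 probe sets with no gene symbol, 100 lower and 9 higher. How much each of these lowered the count of higher calls was not tested. A fold of at least 1.5 left 220, 180 and 40, and an adjusted p under 0.01 left 258, 210 and 48, both stricter by construction. Exact permutation gave 0, 0 and 0 (2540 at an unadjusted p under 0.05), since 252 assignments allow no p under 0.00794 and the smallest adjusted p was 0.180. Without both least correlated arrays (PR+/- 3 and PRKO 3) 99 were higher (349 and 250 differing and lower), with fewer samples. Leaving out 1 pool gave 360 to 488 differing, 265 to 334 lower and 85 to 161 higher. The odds ratio near Pgr was 1.04 within 20 Mb, 2.21 within 10 Mb (Fisher exact p = 0.118) and 0.799 within 40 Mb (p = 0.645), the cause of which was not tested.

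Pgr passed in no setting, and its log2 difference ran from -0.67 to -0.26 without 1 pool. Of the 63 named genes past the threshold, 52 (34 lower, 18 higher) kept their call in every such fit and 11 lost it at least once. With 1 pool left out, named-gene values kept direction and side of the threshold in 1345 cases, lost the call in 64, gained one in 17 and turned in 4. In all other settings these were 1973, 125, 35 and 3. The signs that turned belong to genes that passed nowhere: Plac8 (-0.072 to 0.126 without 1 pool, -0.0061 without both arrays), Fos (-0.027) and Jun (-0.020) with the olfactory covariate, the cause of which was not tested. Of 13 lists past the threshold, 8 lost it without at least 1 pool and 1 kept it with an estimated correlation. The replicate number as a block gave 529, 364 and 165 (439 shared with the 491). Deviations from the genotype means correlated between equal numbers at 0.17, 0.22, 0.32, -0.10 and -0.05, and 2 of 5 matched their own number best. These values do not settle whether equal numbers are pairs. The main fit had no block because that was fixed before the data were examined. Whether equal numbers share a day is not given in the sources used here. Signal over background limits dim genes: of the 491, 16 had both means under the olfactory 95th percentile and 24 had 1.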

Other observations

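All tests in this part were chosen only after the result was seen, and the genes after their values were seen. Glutathione S-transferases of the mu class, which detoxify reactive compounds, included 3 genes that fell among 7 measured. Gstm1 fell by 1.27 (SE 0.10, limma adjusted p = 4.73e-06), Gstm3 by 1.13 (SE 0.10, adjusted p = 1.53e-05) and Gstm2 by 0.75 (SE 0.10, adjusted p = 0.000553) on the log2 scale, n = 5 pools per genotype. All 7 measured members were below 0, with a mean of -0.56 (camera adjusted p = 5.33e-06 over 585 families, adjusted p = 0.992 with an estimated correlation). The mean was -0.57 after quantile normalization. These genes may cross-hybridize, which was not tested on their probes. Among the 40 neighbouring pairs of called genes with the same direction, 34 shared no symbol stem.

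Semaphorins had a mean log2 difference of 0.19 over 20 genes (camera adjusted p = 0.000138, adjusted p = 0.651 with an estimated correlation), 15 of them above 0. Sema7a, a membrane-anchored semaphorin, rose by 0.69 (SE 0.08, limma adjusted p = 0.000103) and Sema4c by 0.34 (adjusted p = 0.0258) on the log2 scale, the Sema4c call being lost without any 1 of 7 pools (all but PR+/- 4 and 5 and PRKO 4, adjusted p up to 0.0699). Ribosomal protein genes had small positive means, 0.18 over 31 Rps genes and 0.14 over 36 Rpl genes (camera adjusted p = 1.61e-06 and 2.40e-06, adjusted p = 0.992 for both with an estimated correlation). Of 585 families tested by symbol stem, 15 passed with camera's preset correlation and 0 with an estimated correlation.

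A hypothesis was that pools differ in how far luteinization had gone. The granulosa cell identity and luteal cell list means correlated across the 10 pools at r = -0.73 (permutation p = 0.0177). After removing genotype means r was -0.94 (permutation p = 0.00012, adjusted over 4 correlations of these same 2 list means 0.00048). That adjustment does not cover the choice of these 2 lists among 34, made after the values were seen. Rank correlations were -0.79 (adjusted permutation p = 0.0111) and -0.95 (0.00096). Without the 2 pools farthest from the median (PRKO 2 and PRKO 3) the values were -0.74 and -0.91. This is consistent with pools taken at different stages of luteinization in both genotypes, although a difference in the mix of cells in the pools could give the same relation and was not tested.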
